A study of Gallus gallus with 25 samples.

How the data were processed

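Small RNA from pooled embryonic chicken gonads was hybridised to 25 one-colour arrays, per the labels. The labels give sex, embryonic day (5.5, 6.5 or 9.5), scan exposure (0.1 to 2 s) and one of 2 array chip numbers, 4011845 (18 arrays) and 50636 (7 arrays). Embryos of days 5.5 and 6.5 had been sexed by PCR and those of day 9.5 by the shape of the gonads, per the labels' protocols. RNA was labelled with a Cy5 dye that binds guanine, so G-rich miRNAs take up more dye, per the labels' protocols. The submitters call the arrays biological replicates, and each came from pooled embryos. Whether replicates numbered 1-1 and 1-2 share a pool is not stated, so p-values measure the spread between these arrays, part of which may be technical.

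The authors deposited scanner output with a median foreground intensity per probe, and a series table of intensity values. Each scanner table holds 1412 probes, of which 657 are perfect-match mature miRNA probes, 657 their partners with 2 mismatched bases, 74 hairpin tiling probes, 17 positive controls and 7 negative controls. No local background values were used here. The mature probes carry the names of chicken (gga, 122 probes), zebrafish (dre, 132), human (hsa, 233), mouse (mmu, 106) and rat (rno, 46) miRNAs, and 18 are the array maker's chicken candidates. A probe named for another species measures whatever chicken RNA binds it, which need not be the miRNA of that name. Such probes were not matched to chicken miRNAs by sequence, so some may have no chicken counterpart and read only related RNA. Each column of the series table was an exact straight line of the scanner medians on that array, with values at or below an array-specific constant (97 to 512) left blank. Its column medians ran from 2507 to 3673. It was therefore a linear background-subtracted and rescaled intensity, not on a log scale or centred by probe, and it was used only as an alternative. How the authors chose the constants is not given in the sources used here.

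Foreground medians were background-corrected with normexp (offset 50) over all spots and put on the log2 scale, and mature probes were quantile-normalised between arrays with limma 3.58.1 in R 4.3.3. Excluded spots were left out. A probe counted as detected where it exceeded the 95th percentile of the 7 negative controls on its array, and was tested if detected on at least 3 arrays, which kept 213 probes (52 of them chicken). One limma model held 6 group means and the chip number as an additive term. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All adjusted p-values are limma's. Group means printed for single probes have the arrays of chip 50636 moved by the fitted chip term. For a probe detected on no array of the dimmer group, a lower bound on the fold was computed from the unadjusted means, with each dim array set to at least the lowest detected probe on it. Such a bound takes no account of the chip, so it is given only at E9.5, where all arrays share one.

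Fixed miRNA lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, and adjusted over lists. Z-linked probes apart, the lists were written from general knowledge of the miRNAs. Of 17 lists, 4 had at least 3 tested chicken probes: the let-7 family, the miR-30 family, the miR-17-92 and paralogous clusters, and miRNAs with every gene copy on the Z chromosome. Z linkage came from the GRCg7b gene table, in which 117 of the 122 chicken probes matched an annotated gene by name. Named probes followed a rule fixed before the data were examined. In each comparison these were the 12 largest called changes in each direction, the 6 lowest p-values where fewer than 6 probes were called, every called member of a list, and miR-202 in all comparisons. The comparisons, the test and most alternatives were fixed then too.

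The procedure was tested on simulated arrays drawn from the real spreads, with 20% of the 213 tested probes changed. In the comparison of the sexes at E9.5, 13.6% of probes changed 2-fold and 41.1% of those changed 3-fold were called. In females from E6.5 to E9.5 the shares were 7.86% and 21.8%. A true log2 change of 1.00 came out at a median of 0.53 in the sex comparison at E9.5, so fold changes are compressed. In 20 unchanged simulations of that comparison, 1 gave a call, as did 2 each for the sexes at E6.5 and for females from E6.5 to E9.5. The simulated noise was independent between arrays and between probes. Deviations shared by arrays were left out, so the error rate and the shares called may differ for the real arrays.

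No 2 arrays held identical values. Same-numbered arrays were checked for shared deviations from the fitted model. At E9.5 all 4 male and female pairs correlated between 0.25 and 0.43, and the 5 male pairs of E5.5 and E6.5 between 0.31 and 0.73, so the numbers were taken to pair the samples there. In the other comparisons at least 1 pair was under 0.1. The alternatives were no background correction, scaling to the 75th percentile of the 19 probes detected on every array, other dim filters, no chip term, each chip alone, the replicate number as a block, merged 1-1 and 1-2 arrays, exposure as a covariate, the series table, fits to the compared groups only, and leaving out each array. Chosen after seeing the data were chip 4011845 normalised and filtered on its own, a filter from the authors' constants, the slide sector as a block, and lists over probes of all species. Hairpin and control probes entered no comparison between groups. Mismatch probes entered only a check of the miR-214, miR-22 and miR-202 differences between the sexes at E9.5.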

Results

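MicroRNA levels were measured in embryonic gonads of male and female chickens during sexual differentiation. There were 5 male and 4 female arrays at E5.5, 5 male and 3 female at E6.5, and 4 of each sex at E9.5. Between 51 and 229 of the 657 mature probes were above the negative controls on an array (median 112). Median foreground intensity ran from 72 to 454 per array, and the number of arrays limits the precision. The chip numbers set the arrays apart more than sex or stage did. The first principal component held 69.8% of the variance and separated the 7 arrays of chip 50636 from the other 18. Pairs of arrays of one group correlated at a median of 0.91 on one chip and 0.21 across chips. The chip term passed the threshold for 194 of 213 tested probes. On chip 50636 the perfect match outshone its mismatch partner in 60 to 72 of the 100 brightest pairs, against 90 to 98 on chip 4011845. All E9.5 arrays were on chip 4011845, and so was only 1 of the 3 female E6.5 arrays.

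**Figure D1:**
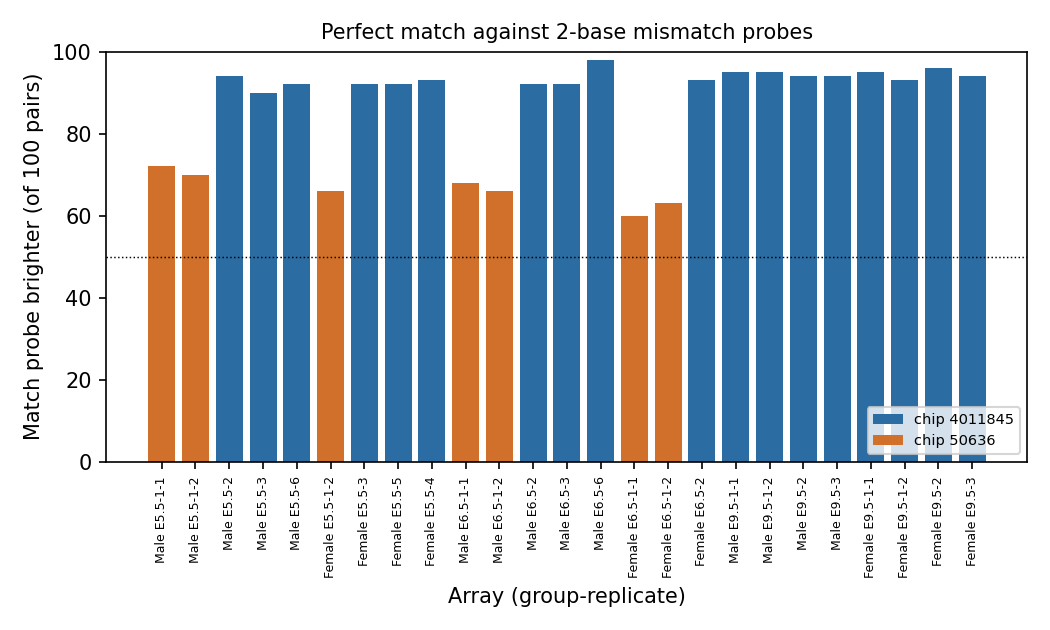
Number of the 100 brightest probe pairs (vertical axis) in which the perfect match exceeded its 2-base mismatch partner, 1 bar per array, coloured by chip number. The 7 arrays of chip 50636 lie between 60 and 72 and the 18 of chip 4011845 between 90 and 98; the dotted line marks 50, where neither is brighter.

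The comparison of the sexes at E9.5, when gonads are visibly different, asked which miRNAs differ between developing testis and ovary. The miR-214 probe (dre-miR-214) was higher in males, at a log2 intensity of 8.42 ± 0.56 (SD, n = 4) against 7.04 ± 0.16 (SD, n = 4), a difference of 1.38 ± 0.32 (SE, limma adjusted p = 0.0216). Both miR-22 probes were higher in females. The hsa-miR-22 probe read 8.19 ± 0.26 (SD, n = 4) in females and 7.36 ± 0.19 (SD, n = 4) in males, and differed by -0.82 ± 0.18 (SE, male minus female, limma adjusted p = 0.0216). The dre-miR-22a probe differed by -0.69 ± 0.16 (SE, limma adjusted p = 0.0216). The dre-miR-22a probe was above the negative controls on no male array and on 3 female ones, and its fold was at least 1.00. That bound leaves room for almost no difference above the detection level, so the size of its difference is not known. Of 211 tested probes with a value on all 8 arrays, 13 had all arrays of one sex beyond those of the other, against 6.03 by chance. That chance value takes the 8 arrays as interchangeable, whereas their replicate numbers were taken to pair them, so it is only a rough guide. The miR-214 probe and both miR-22 probes were the only 3 calls of 213 tested, with 15 probes at an unadjusted p under 0.05. By chance 10.65 would be expected under that cut, in this and in each other comparison.

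MiR-202, a miRNA known from gonads, did not pass the threshold at E9.5 over all groups. The gga-miR-202* and hsa-miR-202 probes were detected on too few arrays to be tested in any comparison. The dre-miR-202 probe read 7.83 ± 0.24 (SD, n = 4) in males and 6.95 ± 0.18 (SD, n = 4) in females, a difference of 0.88 ± 0.26 (SE, limma adjusted p = 0.103). The gga-miR-202 probe differed by 0.99 ± 0.31 (SE, limma adjusted p = 0.157), and the mmu-miR-202 probe, above the negative controls on no array of either sex, by 0.09 ± 0.37 (SE, limma adjusted p = 0.986). The gga-miR-199a probe (0.75 ± 0.22, SE, limma adjusted p = 0.103) did not pass either. With the replicate number as a block, 6 probes were called, among them dre-miR-202 (limma adjusted p = 0.00731), gga-miR-202 (0.0162) and gga-miR-199a (0.0424). That the numbers pair the samples here was inferred from these same arrays and is not stated in the labels. The block also spanned groups where the numbers did not pair, such as the sexes at E5.5 (median correlation -0.15). Both miR-202 probes also passed in a fit of the compared arrays alone (limma adjusted p = 0.0304 for dre and 0.0358 for gga) and with the series values (0.00868 and 0.0187), where dre-miR-22a no longer passed (0.164 and 0.154, within 0.0169 to 0.944 over the alternatives). They did not pass in the other alternatives, leave-outs apart, where the limma adjusted p reached 0.997 for each of the 3 probes. For dre-miR-214 it ran from 0.000252 to 0.995. No probe was called on chip 4011845 alone, with 75th percentile scaling, without the chip term, with 1-1 and 1-2 merged, or with the slide sector as a block. The dre-miR-214 difference was then 1.38 ± 0.35 (SE) on chip 4011845, 1.53 ± 0.40 with that scaling, 1.38 ± 0.49 without the chip term, 1.29 ± 0.41 merged and 1.28 ± 0.32 with sector. That of hsa-miR-22 was -0.82, -0.80, -0.82, -0.83 and -0.74 in the same order, and that of dre-miR-22a -0.69, -0.68, -0.69, -0.63 and -0.57. All E9.5 arrays are on chip 4011845. The differences on that chip alone and without the chip term thus equal those of the fit to all arrays by construction, and only their SE could change. Leaving out Male E9.5 replicate 2 or Female E9.5 replicate 1-2 also left 0 calls, and leaving out any other male array left 1.

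**Figure D2:**
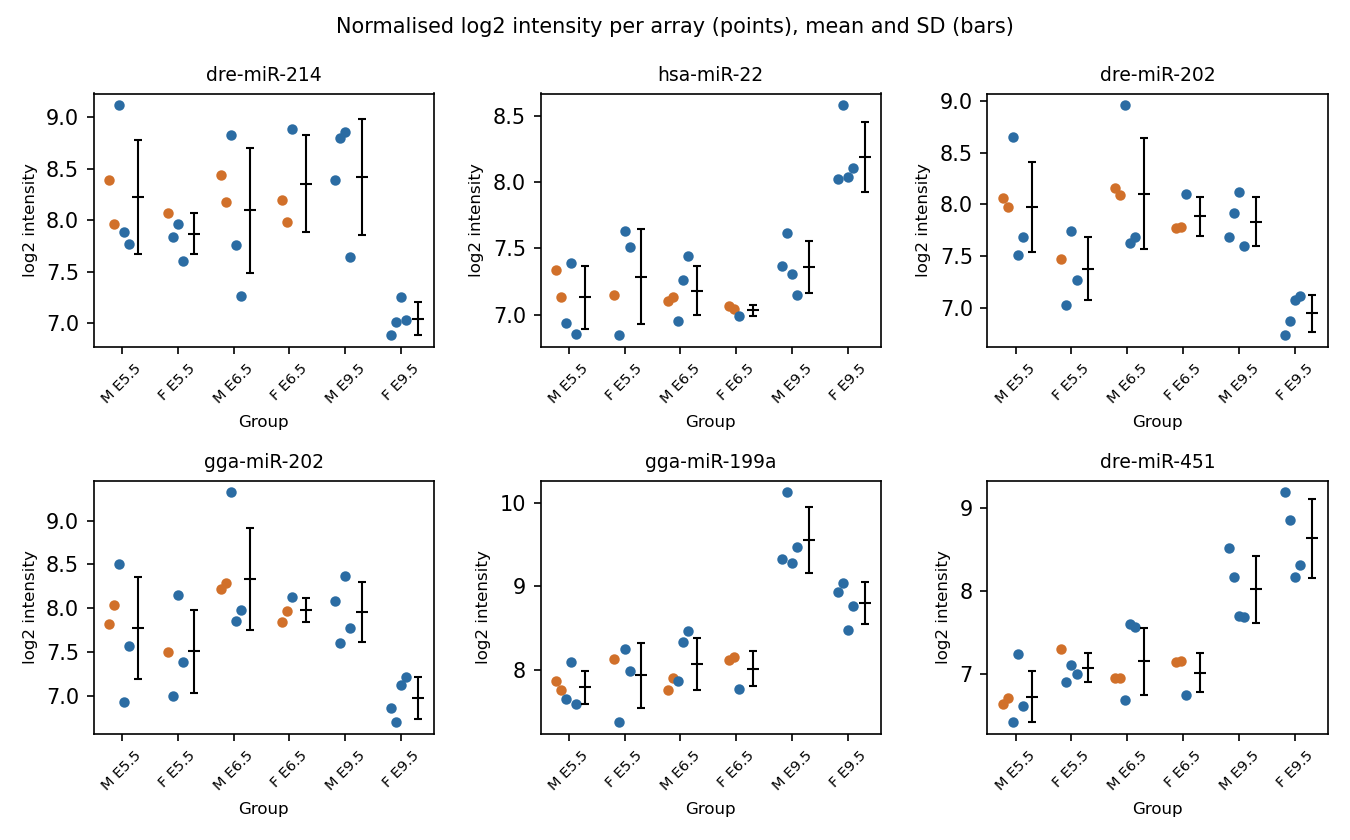
Normalised log2 intensity (vertical axis) of 6 probes in the 6 groups (horizontal axis, M male, F female), 1 point per array, blue for chip 4011845 and orange for chip 50636 after moving by the fitted chip term; bars give mean and SD. At E9.5 the dre-miR-202 means are 7.83 in males and 6.95 in females, and the dre-miR-214 means are 8.42 and 7.04.

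At E5.5, when the embryos were sexed by PCR, the comparison asked whether the sexes differ early. No probe was called between the sexes by limma, and 16 of 213 had an unadjusted p under 0.05. The 6 lowest p-values, none of which passed, belonged to dre-miR-10a (-1.43 ± 0.50, SE, male minus female), dre-miR-430a (0.67), mmu-let-7a (0.53), mmu-miR-326 (0.67), dre-miR-202 (0.60 ± 0.24, SE) and gga-miR-181a (-0.43). The limma adjusted p of all 6 was 0.612, and the mmu-let-7a probe was above the negative controls on no array of either sex. The dre-miR-10a value rests on Female E5.5 replicate 1-2: it was -0.29 ± 0.26 (SE) without that array and -0.27 ± 0.32 (SE) within chip 4011845. That array stood out in quality. Its median foreground was 454, against at most 207 on any other array, and 180 mismatch probes were detected on it, against at most 82 elsewhere. It is the only female E5.5 array on chip 50636, so every fit of that chip alone that involves E5.5 females rests on it. The gga-miR-202 and mmu-miR-202 probes differed by 0.26 and 0.22. Within chip 4011845 alone 0 probes were called. Within chip 50636 alone, where 2 male arrays were compared with 1 female array assumed to vary like the other groups, 46 were.

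At E6.5 no probe was called between the sexes by limma either, with 28 at an unadjusted p under 0.05 and a smallest adjusted p of 0.116. The 6 lowest p-values belonged to hsa-miR-520d* (-0.74), gga-miR-122a (0.49), hsa-miR-527 (-0.76), gga-let-7i (0.67 ± 0.19, SE), dre-let-7d (0.66) and gga-miR-34a (0.51), and none passed. Within chip 4011845, with 1 female array, hsa-miR-520d* was -0.074 and hsa-miR-527 0.040. The other probes were 0.32, 0.77, 0.46 and 0.48 there, in the order given. MiR-202 differed by 0.22 (dre), 0.35 (gga) and -0.29 (mmu). Without Female E6.5 replicate 2, the only array of its group on chip 4011845, 4 probes were called. Within chip 50636 alone 3 were called, and within chip 4011845 alone 0.

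Averaged over the 3 stages, no probe passed between the sexes in limma (24 at an unadjusted p under 0.05). The lowest p was that of dre-miR-202, 0.57 ± 0.15 higher in males (SE, limma adjusted p = 0.180), followed by dre-let-7d (0.37), gga-let-7b (0.38), hsa-miR-520d* (-0.32), the candidate gga_candidate_mmu_297-1 (0.26) and gga-miR-202 (0.53 ± 0.18, SE). The mmu-miR-202 probe differed by 0.01. With the replicate number as a block some probes were called between the sexes averaged over stages, as counted in the section on processing. All 4 tested chicken let-7 probes were higher in males, with a median of 0.24, and the family passed camera (adjusted p = 0.0308). It gave an adjusted p = 0.0962 with an estimated correlation. No member was called over all probes, and 1 was called adjusted over the list alone. The family also passed with 75th percentile scaling, and did not pass without the chip term or with the replicate block. No probe was called within chip 4011845 alone. For the change of the sex difference, limma called 0 probes between E5.5 and E6.5 (13 at an unadjusted p under 0.05) and 0 between E6.5 and E9.5 (21), which does not show that it stayed the same. Without Female E6.5 replicate 2 there were 2 calls in each interval. Within chip 50636 alone there were 41 in the earlier one, and with the replicate block 1 in the later one. In the later interval hsa-miR-22 (-0.97), dre-miR-214 (1.64 ± 0.47, SE), dre-miR-22a (-0.79), dre-miR-196a (-0.79), gga-let-7i (-0.79) and hsa-miR-527 (0.85) had the lowest p-values, none passing (limma adjusted p from 0.167 to 0.279), and miR-202 gave 0.66 (dre), 0.63 (gga) and 0.38 (mmu). In the earlier one these were dre-miR-7a (0.75), gga-miR-181a (0.71), dre-miR-15b (0.68), hsa-miR-422b (-1.20), dre-miR-10a (1.88) and hsa-miR-520d* (-0.63), all at a limma adjusted p of 0.775 (dre-miR-10a 0.53 without Female E5.5 replicate 1-2), and miR-202 gave -0.38 (dre), 0.09 (gga) and -0.51 (mmu).

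From E6.5 to E9.5 in males, 5 of 8 tested probes for miRNAs known from mesenchyme and smooth muscle rose. The gga-miR-199a probe went from 8.06 ± 0.31 (SD, n = 5) to 9.55 ± 0.40 (SD, n = 4), a change of 1.49 ± 0.22 (SE, limma adjusted p = 0.000142), and dre-miR-199* rose by 1.34 ± 0.22 (SE, limma adjusted p = 0.000476). The hsa-miR-145 (1.30), dre-miR-145 (1.17) and dre-miR-143 (0.96) probes rose too, while hsa-miR-143 (0.80), mmu-miR-199b (0.47) and dre-miR-214 (0.33) did not pass. Also called higher were gga-miR-99a (0.94), dre-miR-451 (0.87), a miRNA of red blood cells, and gga-let-7c (0.80). The dre-miR-31 probe fell by 0.70 on the log2 scale. The gga-miR-205b probe was called lower (-0.87) but was above the negative controls on 0 of 4 E9.5 and 2 of 5 E6.5 arrays, so the size of its change is not known. These were all 10 calls, 8 higher and 2 lower. All 4 chicken let-7 probes were higher, with a median of 0.46, and the family passed camera (adjusted p = 0.0232), with an adjusted p = 0.0799 with an estimated correlation. Over all probes 1 was called, and 1 adjusted over the list alone. The family did not pass without the chip term in either sex. MiR-202 changed by -0.27 (dre), -0.38 (gga) and -0.34 (mmu), none passing. On chip 4011845 alone 2 probes were called, dre-miR-199* (1.35) and gga-miR-199a (1.33), with the other differences little moved (hsa-miR-145 1.23, dre-miR-145 1.15, dre-miR-143 0.92, gga-miR-99a 0.94, dre-miR-451 0.74, gga-let-7c 0.86, gga-miR-205b -0.83 and dre-miR-31 -0.77). The 10 probes were picked in a fit that includes the arrays of that chip, so the similar sizes are no independent check. There were 4 calls without the chip term, and leaving out 1 array gave 4 to 10. The count was 4 without Male E6.5 replicate 1-2 or Male E9.5 replicate 1-2, 5 without Male E6.5 replicate 2 or Male E9.5 replicate 1-1, and 6 without Male E6.5 replicate 1-1.

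From E6.5 to E9.5 in females, 31 probes were called higher and 13 lower in the fit of all arrays, but this count rests on few arrays. On chip 4011845 alone, with 1 female E6.5 array assumed to vary like the other groups, no probe was called, and 15 were when that chip was normalised and filtered on its own. The differences of most named probes were not smaller there: the 12 named higher ran from 1.12 (hsa-miR-143) to 1.98 (dre-miR-26b), with dre-miR-451 at 1.89 ± 0.44 (SE, limma adjusted p = 0.0514). Of the 12 named lower, 7 were larger there and 5 smaller, from -3.01 (gga_candidate_dre_130c-1) to -0.015 (hsa-miR-527). The female E6.5 array there is replicate 2, which deviated like Male E5.5 replicate 2 (r = 0.75) and Male E6.5 replicate 2 (r = 0.49). It also deviated like Female E9.5 replicate 2 (r = 0.62) and Male E9.5 replicate 2 (r = 0.44), so the shared deviation was not confined to early arrays. For dre-miR-214 it read 8.89, and the replicate 2 arrays of early males 9.12 and 8.83. The other early male arrays of that chip read 7.26 to 7.89. The larger differences there may thus rest on Female E6.5 replicate 2. With 75th percentile scaling the calls were 8 higher and 12 lower. Among the 31 called higher in the fit of all arrays were dre-miR-451 (1.62 ± 0.30, SE, limma adjusted p = 0.00229), hsa-miR-451 (1.54), dre-miR-26b (1.38), gga-miR-26a (1.18), hsa-miR-22 (1.15), dre-miR-199* (1.13), dre-miR-143 (1.13), hsa-miR-145 (1.11), gga-miR-15b (1.10), hsa-miR-143 (1.09), rno-miR-363-3p (1.09) and dre-miR-15b (1.08). Leaving out 1 array gave 15 calls without Female E9.5 replicate 1-2, 22 without Female E9.5 replicate 1-1, and 24, 24 and 25 without each of the E6.5 arrays. Of the 12 probes named, 8 were detected on no female E6.5 array, so the size of their change is not known exactly. Without Female E6.5 replicate 2 the dre-miR-26b change was 0.88.

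Called lower in females at E9.5 were the candidate gga_candidate_dre_130c-1 (-2.38 ± 0.70, SE, limma adjusted p = 0.0235), mmu-miR-494 (-2.10), dre-miR-214 (-1.31), dre-miR-140* (-1.25), dre-miR-202 (-0.94), hsa-miR-129 (-0.92), gga-miR-205b (-0.89), gga-miR-130b (-0.88), mmu-miR-290 (-0.79), dre-miR-130b (-0.78), hsa-miR-527 (-0.75) and gga_candidate_hsa_222 (-0.69). The gga-miR-205b probe was above the negative controls on no female array of either stage, so its change lies below that level. The hsa-miR-527 and gga_candidate_hsa_222 probes were above them on no E9.5 array, so the size of their change is not known. Whether chicken has miRNAs matching the mouse and human probes named here, such as mmu-miR-494, mmu-miR-290 and hsa-miR-527, was not checked. Within chip 4011845 the difference was -0.015 for hsa-miR-527 and -0.28 for hsa-miR-129, so these calls rest on the 2 E6.5 arrays of chip 50636. Without Female E6.5 replicate 2 these were -1.35 and -1.45, and those of dre-miR-140* and dre-miR-130b were -0.59 and -0.41. The gga-miR-202 probe, at -1.01 ± 0.37 (SE, limma adjusted p = 0.0542), and the mmu-miR-202 probe (-0.72) did not pass. All 4 chicken let-7 probes were called higher: gga-let-7a (0.93), gga-let-7i (0.88), gga-let-7c (0.74) and gga-let-7b (0.67), and all 4 were also called adjusted over the list alone. Within chip 4011845, with 1 female E6.5 array, their changes were 0.58, 0.94, 0.71 and 0.44 in the same order. The family passed camera (adjusted p = 0.0218), and had an adjusted p = 0.0768 with an estimated correlation. Without the chip term gga-let-7b and gga-let-7i turned to -1.40 and -0.65, and of the probes called lower dre-miR-140*, dre-miR-202, gga-miR-205b and gga-miR-130b turned to 0.41, 0.025, 0.060 and 0.22. Of the miR-30 family, gga-miR-30d was called (0.67, detected on no E6.5 array) and camera gave an adjusted p = 0.0970. Gga-miR-199a was called at 0.79. Of the 10 probes called in males, 8 were also called in females, all with one direction. Both comparisons use 1 fitted chip term, so the overlap is not independent. The test of the difference between the sexes called none.

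**Figure D3:**
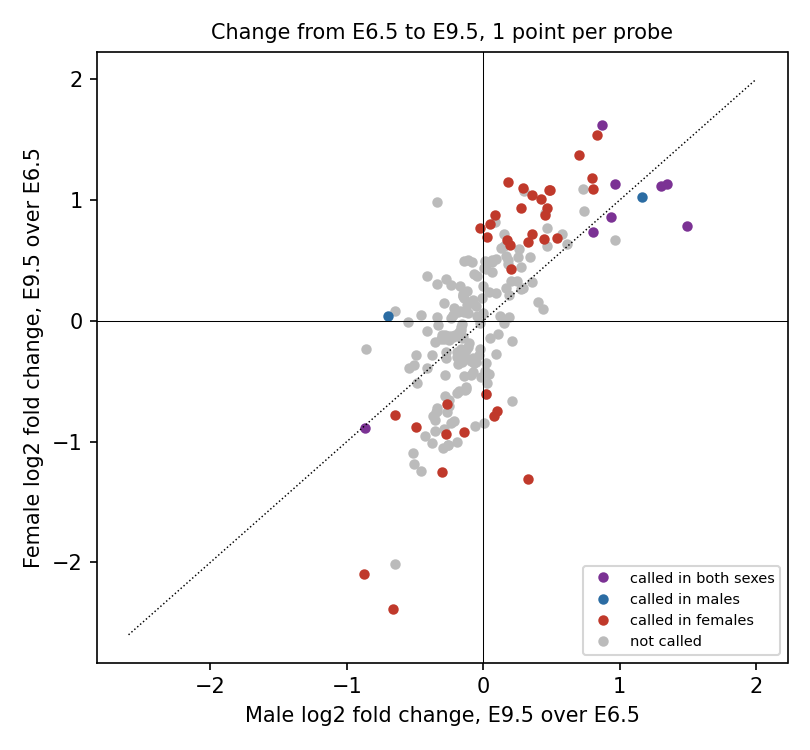
Log2 fold change from E6.5 to E9.5 in males (horizontal axis) and females (vertical axis), 1 point per tested probe (213), coloured by whether it was called; the dotted line marks equal change. The 8 probes called in both sexes include gga-miR-199a, at 1.49 in males and 0.79 in females, and gga-miR-205b, lower in both.

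From E5.5 to E6.5 no probe was called in males (limma, 5 at an unadjusted p under 0.05) or females (17). In males the lowest p-values were those of hsa-miR-373* (-0.94), rno-miR-327 (-0.79), hsa-miR-422b (-0.64), dre-miR-199* (0.44), mmu-miR-370 (-0.32) and gga-miR-202 (0.56), all at a limma adjusted p of 0.991, and dre-miR-202 and mmu-miR-202 gave 0.13 and -0.18. In females they were dre-miR-10a (-1.87 ± 0.59, SE; -0.52 ± 0.31 without Female E5.5 replicate 1-2), hsa-miR-527 (0.71), rno-miR-505 (0.65), hsa-miR-520d* (0.60), hsa-miR-224 (0.77) and gga-miR-181a (-0.59), all at a limma adjusted p of 0.326. Within chip 4011845, with 1 female E6.5 array, these changes were -0.61, -0.045, -0.053, -0.0033, -0.080 and -0.46 in the same order. MiR-202 gave 0.51 (dre), 0.47 (gga) and 0.33 (mmu). Without Female E6.5 replicate 2, 8 probes were called in females. Within chip 50636 alone, with 1 female E5.5 array, 61 were, and within chip 4011845 alone 0.

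The 8 tested chicken probes of the miR-17-92 clusters, known from proliferating cells, the 4 of the miR-30 family and the 3 Z-linked ones (gga-miR-23b, gga-miR-24 and gga-miR-31) passed camera in no comparison of the fit to all arrays. Without the chip term the miR-17-92 clusters passed in 3 comparisons and the miR-30 family in 1, and with 75th percentile scaling the miR-30 family passed in 2. With exposure in the fit the miR-30 family passed in 1. At E9.5 the median sex differences were -0.09, 0.03 and -0.17 (adjusted p = 0.912 for each list, and 0.944 with an estimated correlation), with 0 members called over all probes and 0 adjusted over the list alone. No Z-linked probe was called at E5.5 or E6.5, where the medians were 0.07 and -0.02. In males from E6.5 to E9.5, 2 Z-linked probes were called adjusted over the list alone and 0 over all probes.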

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

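Tests chosen only after their result was seen are the 3 on the separation of the chips and the one on the chip term with different E6.5 arrays; the fit with the slide sector was also chosen after the data were seen.

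The 7 arrays of chip 50636 stood apart from arrays of the same groups on the other chip. A shifted probe order is argued against by the correlation of the mean profiles, 0.58 without a shift and at most 0.24 with one. Sex or stage as the cause is argued against by the low correlation across chips within a group, 0.21 against 0.91 on one chip. Less specific hybridisation is a candidate explanation, since no array of chip 50636 had more than 72 of 100 pairs with the match brighter and none of chip 4011845 fewer than 90. Mismatch and hairpin tiling probes carried signal above the negative controls too: 79 mismatch and 28 hairpin tiling probes were detected on at least 3 arrays.

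Of the probes called in females from E6.5 to E9.5, 100% kept their direction on chip 4011845 alone, with a median ratio of log2 fold changes of 1.13, but that test shares arrays with the fit that picked them and decides nothing. With different E6.5 arrays on each side, 76% of the 25 probes called without Female E6.5 replicate 2 kept their direction, against 71.8% of all tested probes, with a median ratio of 0.48. Part of these calls may come from the chip term, but this test cannot decide it. Both sides share the female E9.5 arrays, and Female E6.5 replicate 2 is the only female E6.5 array on that chip. A lower ratio can also arise because the probes were selected on 1 side. Blood in the tissue stays open: the probes called higher had a mean correlation of 0.26 with miR-451 over the 8 E9.5 arrays, against -0.04 for probes not called, between the bounds set beforehand; dre-miR-451 itself read 8.63 ± 0.48 (SD, n = 4) in females at E9.5 and 7.01 ± 0.23 (SD, n = 3) at E6.5. A change of the female gonad with age stays open, untested.

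For miR-214, miR-22 and miR-202 at E9.5, hybridisation without a full match is argued against by the mismatch partners, whose median ratio of log2 fold change to the match was 0.071 and which were detected on none of the 8 arrays, though a close relative of the miRNA may still bind. Exposure ran from 0.5 to 2 s in both sexes at E9.5. The ratio of the differences with and without exposure in the fit was 1.01. With exposures so alike the fit could hardly change the differences, so the ratio by itself decides little. With the slide sector in the fit, dre-miR-214 went from 1.38 ± 0.32 to 1.28 ± 0.32 (SE) and hsa-miR-22 from -0.82 ± 0.18 to -0.74 ± 0.18. The differences became smaller with a similar spread (limma adjusted p = 0.0653 for both, within 0.000252 to 0.997 over the alternatives, leave-outs apart), so sector stays open for part of the difference, beside the sex of the gonads.

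Other splits of the same arrays were counted. For males from E6.5 to E9.5, 1 of 100 splits, the real one, gave as many (10 calls, next highest 8). For females it was 1 of 35 (44 calls, next 2), the smallest share possible. All E9.5 arrays but only some E6.5 arrays were on chip 4011845, so other splits also change the balance of the chips. These counts argue against a random grouping of the arrays but do not separate stage from chip. At E9.5 the sexes gave 3 calls and the highest other of 35 splits 0, but the replicate numbers were taken to pair these arrays. Only 8 splits part all 4 pairs, too few for a share under 0.05; the real split gave 3 calls and the others 0, and with the replicate block 6 and 0. The male split with 8 calls put Male E6.5 replicate 6 with the 4 E9.5 arrays, the other E6.5 arrays opposite. Where the real count was 0 every split reached it and chance was not excluded: 100 splits each for the sexes at E5.5 (highest other 11), averaged over stages (3) and the changes of the sex difference (33 and 0), 56 at E6.5 (0) and 35 for females from E5.5 to E6.5 (2). Males from E5.5 to E6.5 gave 0 calls, and the highest of 100 splits 40; the 16 splits that part all 5 pairs are too few for a share under 0.05, and all gave 0. Splits calling 40 and 33 probes point to structure among the early arrays beyond sex and stage. The split with 40 calls parted only the pair numbered 1-2 of the 5 male pairs, whereas stage parts all 5, and the comparison by stage kept 0 calls with the replicate block.

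Single arrays far from the rest of their group were Female E9.5 replicate 1-2 for hsa-miR-22 (gap over range 0.852), Female E9.5 replicate 3 for dre-miR-199* (0.836) and Male E9.5 replicate 1-2 for gga-miR-99a (0.864). These are 3 of 80 groups of values examined, where chance gives 4.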

How the results depend on the processing

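Added after seeing the data were chip 4011845 on its own normalisation and filter, the authors' constant as filter, the slide sector and lists over all species; the other settings were planned. Chip 50636 alone gave no value for comparisons with E9.5, of which it holds no array. Unless stated, the cause was not tested. Counts within 1.5 times of the one reported are not repeated.

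For the sexes at E9.5 (3 calls), 0 remained with 75th percentile scaling, without the chip term, within chip 4011845, with 1-1 and 1-2 averaged, with that chip on its own normalisation and with sector; leaving out arrays gave 0 to 3. The replicate block gave 6 calls there, and 5 at E5.5, 5 averaged over stages, 9 for females from E5.5 to E6.5, 6 for males from E6.5 to E9.5 and 1 for the change of the sex difference to E9.5. For males from E6.5 to E9.5 (10 calls) there were 4 without filter, 4 without chip term, 2 within chip 4011845, 2 with its own normalisation, 3 with averaged replicates, 1 with series values, 5 with only the compared groups and 4 to 10 leaving out arrays. For females (44 calls) there were 20 with 75th percentile scaling, 0 within chip 4011845 (1 array in an arm), 15 with its own normalisation, 5 with averaged replicates (fewer samples), 14 with series values and 15 to 42 leaving out arrays. Of comparisons with 0 calls, no filter gave 1 at E6.5 and 4 for females from E5.5 to E6.5, series values 1 for males from E5.5 to E6.5, and chip 50636 alone 46 at E5.5, 3 at E6.5, 61 for females and 41 for the change of the sex difference to E6.5. Leaving out arrays gave 0 to 4 at E6.5 and averaged over stages, 0 to 8 for females from E5.5 to E6.5 and 0 to 2 for both changes of the sex difference, the highest each time without Female E6.5 replicate 2. The lists (3 calls) gave 6 with 75th percentile scaling and 24 over all species. That scaling moved the median of all probes by 0.20 and -0.15 between the sexes at E5.5 and E6.5, 0.38 and -0.23 in females to E6.5 and to E9.5, and -0.35 and 0.13 in the changes of the sex difference.

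Of the called values under an alternative, 512 kept direction and side of the threshold, 395 kept direction only and 6 turned direction, all without the chip term in females from E6.5 to E9.5: dre-miR-140* (0.41), dre-miR-202 (0.025), gga-miR-205b (0.060), gga-miR-130b (0.22), gga-let-7b (-1.40) and gga-let-7i (-0.65). Probes not called that turned without it were gga-miR-34a at E6.5 (-0.20), dre-miR-202, gga-miR-202 and mmu-miR-202 in females to E6.5 (-0.095, -0.18, -0.059) and in males to E9.5 (0.30, 0.25, 0.031), gga-miR-202 in females to E9.5 (0.034), and dre-miR-7a and dre-miR-202 in the change to E6.5 (-0.31, 0.22). Within chip 4011845 these were hsa-miR-527 and dre-miR-202 at E6.5 (0.040, -0.014), mmu-miR-202 averaged (-0.25, the same with its own normalisation), and hsa-miR-527, rno-miR-505, hsa-miR-520d* and hsa-miR-224 in females to E6.5 (-0.045, -0.053, -0.0033, -0.080). Within chip 50636 they were mmu-miR-202 at E5.5 (-0.28), at E6.5 (0.25), in females to E6.5 (-0.63) and in the change to E6.5 (0.53), with gga-miR-202 there at -0.079. Mmu-miR-202 turned with the replicate block at E5.5 (-0.13), E6.5 (0.013), averaged (-0.0089), in females to E6.5 (-0.32) and in the change to E6.5 (0.15), and averaged over stages with 75th percentile scaling (-0.072), averaged replicates (-0.083) and exposure (-0.012). With sector it turned at E5.5 (-0.14), averaged (-0.15) and in males to E6.5 (0.11), as did dre-miR-202 and gga-miR-202 at E6.5 (-0.13, -0.014) and gga-miR-202 in the change to E6.5 (-0.41; -0.28 with 75th percentile scaling). In the series table dre-miR-10a turned at E5.5 (0.22) and mmu-miR-202 at E9.5 (-0.86) and in the change to E9.5 (-0.81). Leaving out arrays, mmu-miR-202 ran from -0.18 to 0.47 at E5.5, -0.50 to 0.29 at E6.5, -0.11 to 0.19 averaged, -0.38 to 0.19 in males and -0.29 to 0.63 in females to E6.5, -0.80 to 0.12 and -0.20 to 0.59 in the changes; dre-miR-202 from -0.10 to 0.31 in males to E6.5 and -0.43 to 0.00071 to E9.5; and gga-miR-202 from -0.18 to 0.33 in the change to E6.5. Probe brightness near the negative controls limits the weakest of these.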

Other observations

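The array shares sequences between species under a single name, so the lists were also run over probes of all species, an alternative chosen after seeing the data. Probes for one miRNA are then not independent. Of 90 list tests 24 passed camera, and only the first below held with an estimated correlation. The 8 mesenchymal and smooth muscle probes were all higher at E9.5 than E6.5 in males, with 5 called over all probes, 6 adjusted over the list alone and a median of 1.06 (camera adjusted p = 3.04e-11, and 9.1e-05 with an estimated correlation). In females 5 were called higher and 1 lower, and 8 adjusted over the list alone (adjusted p = 0.00903, and 0.0889 with an estimated correlation). The 8 tested gonad and testis probes are for miR-140*, miR-202 and miR-204 only. They were all higher in females at E6.5 than E5.5, with a median of 0.40 and 0 called over all probes or adjusted over the list alone (adjusted p = 0.0497, and 0.241 with an estimated correlation). From that same group of 3 E6.5 arrays they were all lower in females at E9.5 than E6.5, with a median of -0.85, 2 called and 3 adjusted over the list alone (adjusted p = 0.00900, and 0.0889 with an estimated correlation), and all were higher in males than females at E9.5, with a median of 0.26, 0 called over all probes by limma and 2 adjusted over the list alone (adjusted p = 0.00386, and 0.134 with an estimated correlation). Of the 18 probes of the miR-17-92 clusters, 14 were lower and 4 higher in males at E9.5, with a median of -0.26 (adjusted p = 0.00386, and 0.256 with an estimated correlation). In the change of the sex difference to E9.5, 17 were negative and 1 positive, with a median of -0.43 (adjusted p = 0.0173, and 0.310 with an estimated correlation). Limma called 0 of them in both comparisons, over all probes and adjusted over the list alone. The 6 miR-30 probes were all higher at E9.5 than E6.5, with a median of 0.41 in males (adjusted p = 0.0120, and 0.356 with an estimated correlation) and 0.65 in females (adjusted p = 0.0362, and 0.260 with an estimated correlation). The other lists that passed are given with the p under an estimated correlation last. The mesenchymal list was higher in males at E9.5, with a median of 0.39, 1 called and 2 adjusted over the list alone (adjusted p = 0.00386 and 0.134). The gonad list was higher in the change of the sex difference to E9.5, with a median of 0.59 (adjusted p = 0.00832 and 0.233). The 3 tested neural probes are all for miR-124, so they stand for 1 miRNA and not for a set of neural markers. They were all lower in males at E5.5 (median -0.50, adjusted p = 0.0403 and 0.374), at E6.5 (-0.64, 0.0121 and 0.199) and averaged over stages (-0.38, 0.00756 and 0.279). They were also lower in females at E9.5 than E6.5 (-0.83, 0.0420 and 0.260), with 0 called over all probes and 3 adjusted over the list alone. The 7 Hox cluster probes passed as higher in males at E6.5 (median 0.33, adjusted p = 0.0175 and 0.192), as lower in females at E6.5 than E5.5 (-0.33, 0.0497 and 0.241) and as lower in the change of the sex difference to E9.5 (-0.37, 0.0447 and 0.269). The 9 let-7 probes passed as higher in males at E5.5 (0.24, adjusted p = 0.0403 and 0.374), at E6.5 (0.29, 0.0175 and 0.192) and averaged over stages (0.20, 0.00756 and 0.246). They also passed as higher in males at E6.5 than E5.5 (0.26, 0.0143 and 0.239), and at E9.5 than E6.5 in males (0.45, 0.0120 and 0.187) and females (0.69, 0.00900 and 0.0889).

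The miR-451 probes, from red blood cells, were lower in males than females at E9.5 by a log2 value of -0.62 (dre) and -0.56 (hsa), and neither passed (limma adjusted p = 0.482 and 0.731).

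One negative control read a median of 1.89 times the array median on chip 4011845 and 1.07 times on chip 50636, and another 1.01 and 2.15 times. The detection threshold is set by different controls on the 2 chips.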
